A study of Homo sapiens with 2 samples.

How the data were processed

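R-loops, structures in which RNA pairs with the DNA template strand, were profiled by CUT&Tag in wild-type A549 cells, an established human lung cancer line. In CUT&Tag, an antibody bound to permeabilised cells or nuclei tethers a transposase that cuts nearby DNA and tags it for sequencing. Per the labels, there were 2 libraries, 1 with S9.6, an antibody that binds RNA-DNA hybrids, and 1 with non-specific IgG. The S9.6 library had a peak list, and the IgG library was not analysed here. With 1 library per antibody there was no replicate, and libraries were not tested against each other. Intervals and p-values describe this peak list and cover counting error only.

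The deposited peak list holds, for each peak, a total signal and a maximum coverage that the authors' peak caller wrote as whole numbers, with no sign of scaling to sequencing depth. Its 6 columns have the layout of SEACR, which calls peaks from blocks of continuous coverage and reports the summed signal, the highest coverage and the region where it lies. The units were read from the values: in 47810 of 47810 peaks the total was at most the width multiplied by the maximum, and no adjacent peaks overlapped. The submitters' processing notes name fastp 0.23.2, Bowtie2 2.4.2, SAMtools 1.9, bedtools 2.30.0, SEACR 1.3 and deepTools 3.5.2, with the build GRCh38. They give no roles or order, and the peak-calling threshold, the use of the IgG library as control, and the treatment of duplicate and multiply mapping reads are not given in the sources used here. The sequence names include patches and alternate haplotypes, so reads from a region present in several copies had more than 1 place to map. The total number of reads is unknown, and a gene without a peak may still have signal under the authors' threshold.

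Peaks on chromosomes 1 to 22 and X entered the tests. Gene positions came from a RefSeq table of GRCh38.p14 with the span and class of each gene, 59098 genes on these chromosomes, among them 19974 protein-coding genes and 18177 lncRNA genes. The table gave no strand, exons, transcripts or sequence. The planned test of promoters was therefore replaced by gene boundaries, meaning within 1000 bp of either end of a gene's span, and starts were not told apart from ends. Planned results on gene ends, GC skew, GC content and G-quadruplex motifs were not made. Matching on promoter GC content was replaced by matching on gene class, gene length in 5 bins and gene density in 5 bins, counted as protein-coding genes within 1 Mb. For matching, snRNA, snoRNA and some other small RNA genes were pooled as a single class. GC content and expression were not matched.

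The share of peaks with at least 1 base at a boundary of a protein-coding or lncRNA gene was compared with 100 shuffles of the same peaks within their chromosome. Spans of at least 1 Mb with neither a gene nor a peak, 115 Mb in all, were left out of the shuffle in place of assembly gaps. The one-sided permutation p was taken from the tail on the observed side and is at least 0.0099 with 100 shuffles. Each summit, the middle of the authors' maximum region, was given 1 class: at a boundary, inside a gene or between genes. A second background moved each peak by 10 to 500 kb. Shares of genes carry 95% Wilson intervals. The position of summits was taken at boundaries of protein-coding genes of at least 10 kb with no other boundary within 2000 bp, and the inside share was set against equal shares by an exact two-sided binomial test.

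Before the data were examined, 23 gene lists were fixed, and 1512 of 1512 listed symbols or pattern matches were found in the gene table. For each list, the share of members with a boundary peak, and the share with any peak from 1000 bp before to 1000 bp after the gene span, was compared with 10000 random lists of the same size and matching. These permutation p-values are two-sided, cannot go below 0.0002, and were adjusted by Benjamini-Hochberg over the 23 lists of each test with a threshold of 0.05. The median maximum coverage of the strongest boundary peak per gene was compared with 10000 random lists of genes that have a boundary peak. These were matched on gene class and gene density but not on length. Lists with fewer than 3 such genes were left out, so with higher peaks fewer than 23 lists were adjusted together. Genes are not replicates, so a list's p describes this library. Chromosomes were compared with matched protein-coding genes of the other chromosomes by 10000 random draws. Genes named in the text were chosen by a rule fixed in advance. It took every member of the lists of m6A factors and of loci used in DRIP-qPCR. From every other list it took the 3 members with the highest boundary peak and the first 3 without one in alphabetical order. It also took the 20 genes with the highest boundary peak, the 10 peaks with the highest total signal and the 5 genes with most peaks. Not every gene this rule chose is named in the text, and other names were chosen after their values were seen.

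The code was tested on simulated data. When 10% and 20% of the 45756 peaks were moved onto gene boundaries in 20 simulated sets each, the mean estimates were 10.0% and 20.0%. With none moved the mean estimate was 0.0065%, and 2 of 20 sets lay above all of 20 shuffles. The same 20 shuffles served for every set, so these comparisons are not independent. Among 19974 protein-coding genes, random lists of 30 were called in 5.0% of 200 trials at an unadjusted p of 0.05. Lists of 30 given a planted share of 60% were called in 54.0% of 200 trials, and those given 80% in 100% of trials. These trials drew genes at random and matched on random numbers in place of gene density. Their rates therefore do not cover lists of clustered genes. Alternatives covered higher peaks, other windows, summits in place of whole peaks, protein-coding genes alone and unmatched lists. Others, chosen after the data were seen, were the local shift, matching on surrounding peaks, and lists without chromosome 6. So were lists without genes of the major histocompatibility complex or the leukocyte receptor complex. Other regions with alternate haplotypes or patches were kept. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.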

Results

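The series concerns YTHDF1, a cytoplasmic reader of N6-methyladenosine (m6A) that its title places at R-loops, and the link between R-loops and innate immunity. The library examined here used S9.6, which binds RNA-DNA hybrids, in unperturbed A549 cells. The peak list held 47810 peaks, of which 45756 (95.7%) lay on chromosomes 1 to 22 and X, where they covered 34.6 Mb. Their median width was 685.5 bp and their median total signal 986. Coverage was shallow, with a median maximum coverage of 2. Of these peaks, 24955 (54.5%) reached a maximum of 2, 4365 (9.54%) reached at least 5 and 633 (1.38%) at least 10. The S9.6 list was described by itself, with neither an IgG track nor an RNase H-treated library beside it, so hybrid-dependent and antibody-independent tagging were not separated.

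The first question was where in relation to genes the S9.6 signal lay. S9.6 peaks were concentrated at gene boundaries: 23.2% of peaks touched the 1000 bp around an end of a protein-coding or lncRNA gene, against 7.40% ± 0.117 (SD over 100 shuffles), a ratio of 3.14 ± 0.0495. None of the 100 shuffles was as high (permutation p = 0.0099, the smallest that 100 shuffles can give). Shifting peaks by 10 to 500 kb, which keeps them in their neighbourhood, gave 10.2% ± 0.150 and a ratio of 2.29. By summit, 20% of peaks lay at a boundary against 5.54% after shuffling, 50.6% inside genes against 53.6%, and 29.4% between genes against 40.8%. The ratio inside genes, 0.943, turned to 1.03 when protein-coding genes alone were used.

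Higher peaks lay at gene boundaries more often. The boundary share was 13.1% among 24973 peaks with a maximum coverage of 1 or 2, 24.7% among 12314 peaks at 3, and 40.3% among 4104 peaks at 4. It was 62.2% among 3732 peaks at 5 to 9 and 57.2% among the 633 peaks at 10 or more. The ratio to the local shift rose from 1.45 ± 0.0288 in the lowest class to 4.94 ± 0.207 at 5 to 9, and was 4.08 ± 0.455 at 10 or more. In every class none of the 100 shifts was as high (permutation p = 0.0099, the smallest possible).

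**Figure D1:**
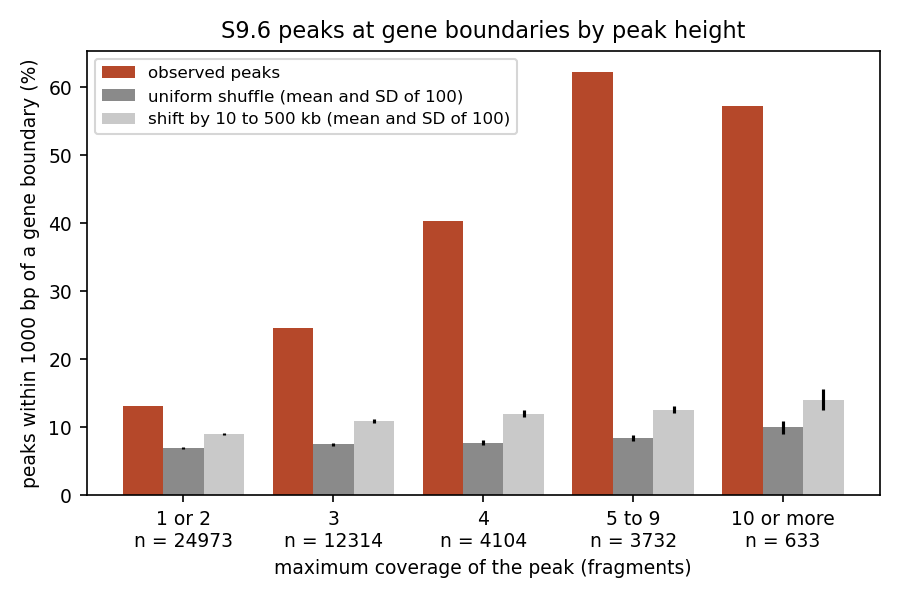
Share of S9.6 peaks within 1000 bp of a gene boundary (percent) by maximum coverage in fragments, beside the mean and SD of 100 uniform shuffles and of 100 shifts by 10 to 500 kb. The observed share is 13.1% in the lowest class and 62.2% at a maximum of 5 to 9.

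Around isolated boundaries of protein-coding genes of at least 10 kb, summits gathered close to the boundary itself. Of 2842 summits, 617 lay within 200 bp outside the gene and 493 within 200 bp inside it, while the outermost bins held 111 and 184. The inside share was 48.9% (95% interval 47.1 to 50.7), not distinguishable from equal shares (exact binomial p = 0.253). It was lower among higher peaks, at 46.7% for the 22878 highest (exact binomial p = 0.00271) and 38.8% for the 4575 highest (exact binomial p = 1.26e-10). Taking the middle of each peak in place of its summit put 53.1% inside the gene, on the other side of equal shares (exact binomial p = 0.000847), so the side depended on the point chosen. Among 14316 protein-coding genes of this length, 35.8% had a peak at 1 boundary and 4.91% at both. The 703 genes with both compared with 745 expected from the rates of lower and upper boundaries. These rates mix starts with ends, so the comparison does not decide whether peaks at a gene's start and end are independent. A peak anywhere over the span was found for 67.2% of these genes.

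**Figure D2:**
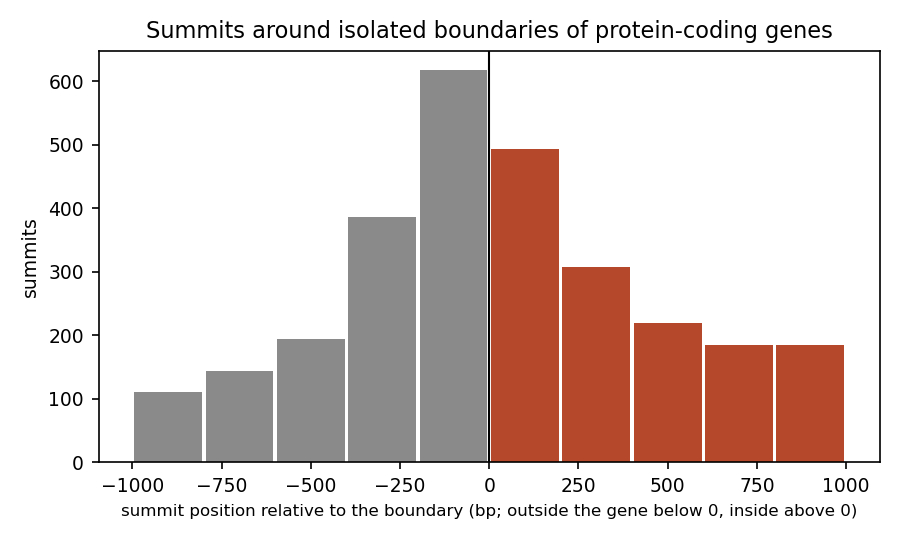
Number of S9.6 summits per 200 bp around isolated boundaries of protein-coding genes of at least 10 kb, with positions outside the gene below 0 and inside above 0 (bp). The bins next to the boundary hold 617 summits outside and 493 inside.

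Gene classes differed in how often they carried a boundary peak. Protein-coding genes did so in 8001 of 19974 cases (40.1%, 95% interval 39.4 to 40.7), 2.75 times the local-shift mean. For lncRNA genes the share was 18.1%, or 1.83 times that mean. Among short RNA genes, tRNA genes, which RNA polymerase III transcribes, had a peak in 194 of 443 cases (43.8%, ratio 5.75) and snRNA genes in 58 of 154 (37.7%, ratio 3.45). Genes for rRNA had 31 of 49 (63.3%, ratio 4.31) and miRNA genes 18.3% (ratio 2.17). The snoRNA genes had 9.70% (ratio 1.47). Transcribed pseudogenes had 25.2%, whereas other pseudogenes had 5.68%. That was below all 100 local shifts (mean 6.42%) but not apart from the uniform shuffle (mean 5.90%, 9 of 100 as low). Immunoglobulin and T cell receptor V segments had 6.45%, close to the 6.22% after shifting. Many tRNA, rRNA and snRNA genes have near-identical copies, so the copy a fragment came from is uncertain. A single peak can also count for several genes, as one over both RNA28SN2 and RNA45SN2, so such genes are not independent counts.

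**Figure D3:**
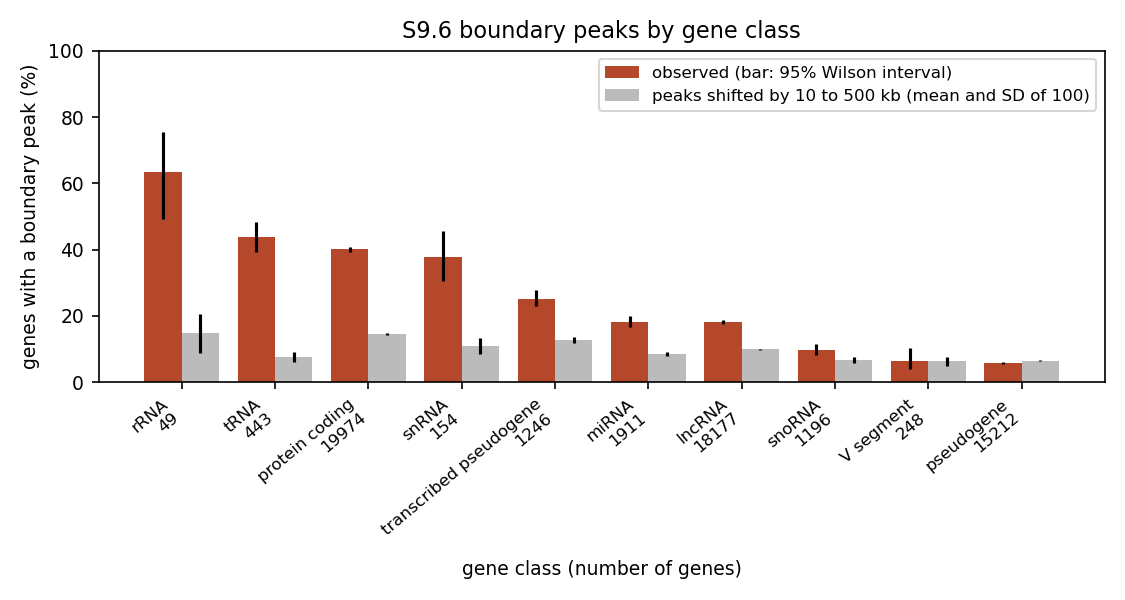
Genes with an S9.6 peak within 1000 bp of a boundary (percent, with 95% Wilson intervals) by gene class, beside the mean and SD of 100 shifts of the peaks by 10 to 500 kb. Protein-coding genes reach 40.1% and tRNA genes 43.8%, while pseudogenes are at 5.68%.

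YTHDF1 itself, on chromosome 20 from 63195429 to 63216131, had no peak at either boundary. Its single peak, at 63210239 to 63210693 inside the gene span, was 455 bp wide with a maximum coverage of 2 and a total signal of 755. Among all 21 m6A readers, writers and erasers, 12 had a boundary peak (57.1%, 95% interval 36.5 to 75.5) against 40.9% in matched lists, which did not pass the test (p = 0.189, adjusted permutation p = 0.256). The highest were at the demethylase ALKBH5 (maximum coverage 16), HNRNPA2B1 (13), the methyltransferase complex member RBM15 (12) and HNRNPC (8). IGF2BP1 and IGF2BP3 reached 6, and the reader YTHDF3 and the writer subunit WTAP reached 5. The catalytic subunit METTL3 and CBLL1 had 4, and METTL16 and RBM15B had 3. FTO carried 5 peaks inside its span, and IGF2BP2 and VIRMA 1 each, without a boundary peak. No peak was listed over YTHDF2, YTHDC1, YTHDC2, METTL14 or ZC3H13. The list passed as higher in 2 of 10 alternative settings, both restricted to higher peaks, and not in the other 8. With peaks of maximum coverage 3 or more, a setting chosen after the data were seen, 12 of 21 stood against 32.7% (p = 0.0346, adjusted permutation p = 0.0497).

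Genes of innate and adaptive immunity were next. Of 26 nucleic acid sensing genes, 11 had a boundary peak (42.3%), close to the 42.1% of matched lists (p = 1, adjusted permutation p = 1). IRF3, a transcription factor activated downstream of cGAS and RIG-I, had the highest (8), followed by SAMHD1 and the adaptor MYD88 (4 each). The DNA sensors CGAS and AIM2 had no peak, and DHX58 had 1 inside its span. Of 36 interferon-stimulated genes, 9 had a boundary peak (25%, 95% interval 13.8 to 41.1) against 41.5% (p = 0.0588, adjusted permutation p = 0.0966). ISG20 reached 4, IFI35 and HERC5 reached 3, and BST2, CCL5 and CXCL10 had none. This list passed as lower in 2 of 10 alternative settings, both restricted to higher peaks, and not in the other 8. With peaks of maximum coverage 3 or more, 5 of 36 interferon-stimulated genes (13.9%) stood against 33.2% (p = 0.0170, adjusted permutation p = 0.0292).

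Immune checkpoint ligands had a boundary peak in 5 of 16 cases (31.2%) against 42.2% (p = 0.535, adjusted permutation p = 0.615). CD274, which encodes PD-L1, had a peak of maximum coverage 4 on chromosome 9 at 5450351 to 5450868, and PVR also had 4. A peak of 30 on chromosome 19 at 44890214 to 44891433 counted for NECTIN2 and for its neighbour TOMM40, whose boundary it spans. CD24, on chromosome 6, and CD276 had 1 peak each inside their spans, and CD80 had none.

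Antigen presentation genes split by position. None of the 13 members in the major histocompatibility complex (MHC) on chromosome 6 had a peak at a boundary or over the span. Of the 11 members elsewhere, 8 had a boundary peak (72.7%, 95% interval 43.4 to 90.3), against 45.2% in matched lists, which did not pass the test (p = 0.121, adjusted permutation p = 0.163). Their highest peaks were at the peptidase ERAP1 (10), the chaperone CALR (8) and TAPBPL (5). CD74 and ERAP2 had none. The whole list, 8 of 24, did not pass at boundaries (p = 0.237, adjusted permutation p = 0.286). Over gene spans it was lower, 33.3% against 60.5% (p = 0.0102, adjusted permutation p = 0.0195), a call that ended in 6 of 7 alternative settings, among them the one without MHC and LRC genes (adjusted permutation p = 0.936). In the MHC, from 28541937 to 33558719, chromosome 6 carried 5 peaks, while 7 alternate MHC haplotypes among the mapped sequences carried 26.

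Housekeeping, immediate early, snoRNA host and ribosomal protein genes carried boundary peaks far more often than matched genes. The list of housekeeping, glycolysis and translation genes had them in 23 of 25 cases (92.0% against 41.1%), with maxima of 10 at ENO1 and 9 at ACTG1 and LDHA. The exceptions were HPRT1 and TUBB, which lies in the MHC. Immediate early and AP-1 genes had 19 of 24 (79.2% against 37.9%), with 14 at EGR1, 12 at JUND and 8 at FOS. ATF3 and EGR2 had peaks inside their spans without a boundary peak, and IER3, in the MHC, had none. Host genes of snoRNAs had 18 of 23 (78.3% against 27.6%), with 11 at ZFAS1, 10 at GAS5 and 9 at NOP56, and none at SNHG1, SNHG5 or SNHG32. SNHG5 lies on chromosome 6 and SNHG32 in the MHC. Cytosolic ribosomal protein genes had 50 of 79 (63.3% against 37.3%), with 24 at RPS19, 9 at RPL28 and 8 at RPL36. RPL11 and RPL14 had no peak, and RPL21 had 1 inside its span. Each of these 4 lists had p = 0.0002, the smallest that 10000 random lists can give (adjusted permutation p = 0.000657).

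Heat shock and chaperone genes followed with 14 of 18 (77.8% against 38.9%; p = 0.00240, adjusted permutation p = 0.00613), with 13 at STIP1 and 8 at HSPA8 and HSPA5. BAG3 and DNAJB1 had peaks inside their spans alone, and HSPA1A, in the MHC, had none. Cell cycle and replication genes had 19 of 30 (63.3% against 39.0%; p = 0.00980, adjusted permutation p = 0.0205), with 12 at PCNA and CDK2 and 8 at MCM7, and none at BUB1, CCNA2 or CCNB1. Boundary peaks can lie wholly outside the gene they count for, as at CDK2 and FOS, and may belong to a neighbour. R-loop processing factors had 20 of 33 (60.6% against 40.1%; p = 0.0250, adjusted permutation p = 0.0460), with 9 at topoisomerase TOP1 and 8 at the helicases AQR and DDX5. ARID1A and BRCA2 had no peak and DDX21 had 1 inside its span. Targets of NRF2, a regulator of antioxidant genes that is active in A549 cells, had 20 of 34 (58.8% against 39.0%; p = 0.0260, adjusted permutation p = 0.0460), with 9 at NQO1 and 8 at FTL and SRXN1. ABCC1, AKR1C1 and AKR1C2 had peaks inside their spans alone. The calls of R-loop factors and NRF2 targets were close to the threshold: they ended in 5 and 6 of 10 alternative settings, with adjusted permutation p-values up to 0.105 and 0.134. In those settings the ratios to matched lists were 1.39 to 1.96 for R-loop factors and 1.40 to 2.04 for NRF2 targets, against 1.51 for both. The call of cell cycle genes ended in 2 of 10, with matching on the number of surrounding peaks (ratio 1.47, adjusted permutation p = 0.0695) and without chromosome 6 (ratio 1.54, adjusted permutation p = 0.0610), against a ratio of 1.62.

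Spliceosomal and other small structured RNA genes stood out in share and height. A boundary peak was found for 25 of 31 (80.6%, 95% interval 63.7 to 90.8) against 24.0% (p = 0.0002, the smallest possible, adjusted permutation p = 0.000657). Their median maximum coverage of 7 compared with 3 in matched lists (p = 0.00140, adjusted permutation p = 0.0322). The matched lists pooled snRNA with snoRNA and other small RNA genes, whereas most members of this list are snRNA genes. Over all genes, 37.7% of 154 snRNA genes and 9.70% of 1196 snoRNA genes had a boundary peak. Both contrasts therefore set snRNA genes in part against snoRNA genes. RNU2-2 reached 13, and RNU4-1 and RNU4-2 shared a peak of 12, while RNU5F-1, RNU6-1 and RNU6-2 had none. Among the 22878 highest peaks the median was still 7, against 4 in matched lists, and the difference no longer passed (adjusted permutation p = 0.328).

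**Figure D4:**
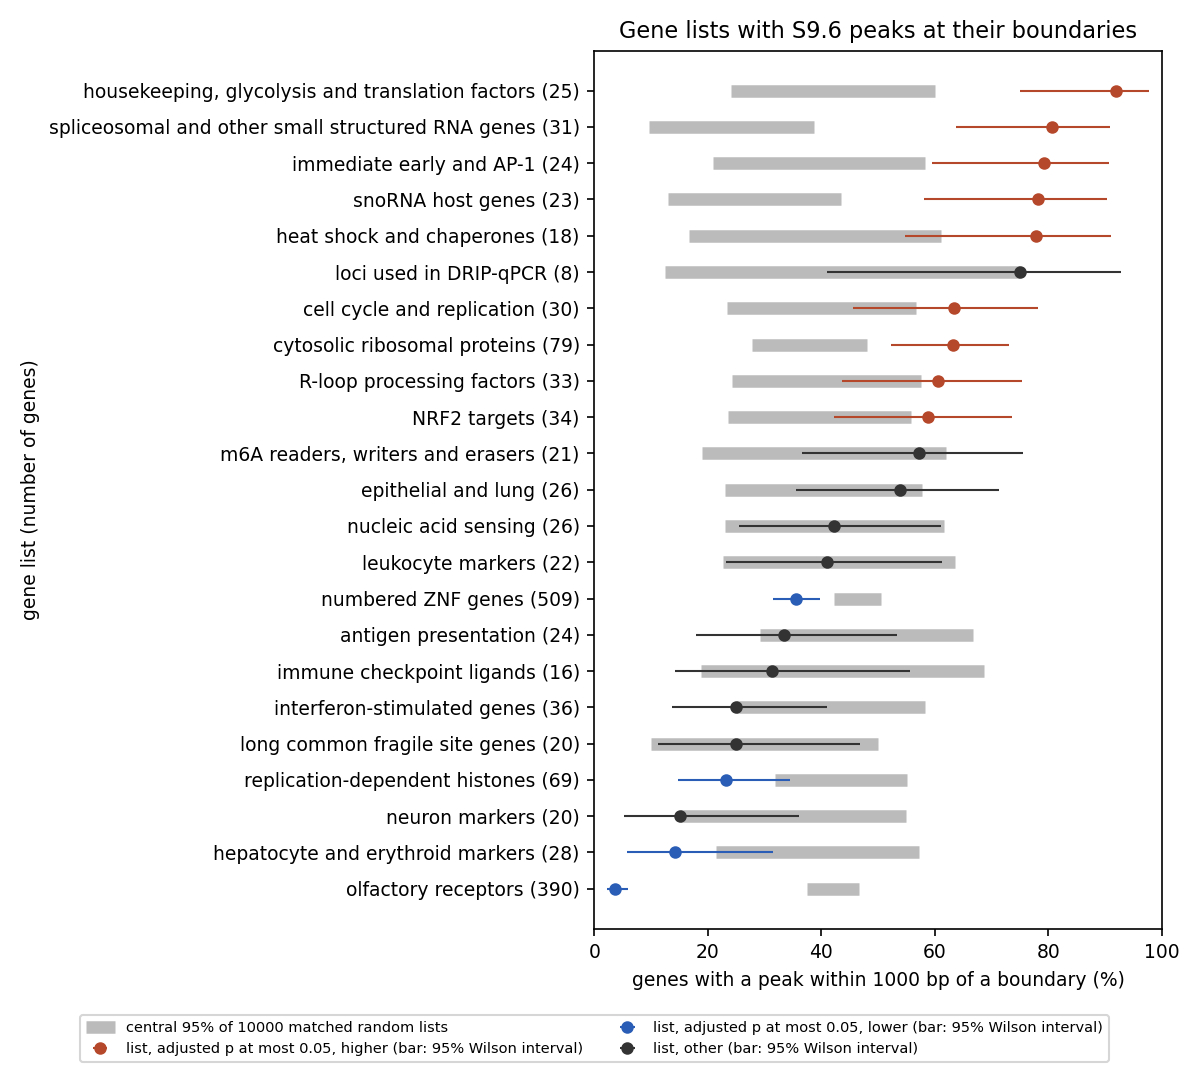
Share of genes in each of 23 lists with an S9.6 peak within 1000 bp of a boundary (percent, points with 95% Wilson intervals), beside the central 95% of 10000 matched random lists in grey. Red points are lists above and blue points lists below the matched lists at an adjusted p of at most 0.05, from 92.0% for housekeeping genes to 3.59% for olfactory receptors.

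Among genes typical of single tissues or cell types, 2 lists were lower and 3 did not pass the test. Olfactory receptors had 14 of 390 (3.59% against 42.0%; p = 0.0002, the smallest possible, adjusted permutation p = 0.000657), the highest being OR1F1 with 4. Their median maximum coverage was 2 against 4 (p = 0.00420, adjusted permutation p = 0.0483), a call lost among the 22878 highest peaks (adjusted permutation p = 0.871). Hepatocyte and erythroid markers had 4 of 28 (14.3% against 39.4%; p = 0.00660, adjusted permutation p = 0.0152), with 3 at F2 and 2 at HBA1 and TF, and none at AHSG, ALAS2 or ALB. This call ended in 2 of 10 alternative settings, with ratios to matched lists of 0.435 with matching on surrounding peaks (adjusted permutation p = 0.0698) and 0.411 with windows of 500 bp (0.0623), against 0.362. Neuron markers had 3 of 20 (15% against 35.6%; p = 0.0664, adjusted permutation p = 0.102), TUBB3 (12), RBFOX3 and SNAP25 (2 each). They passed as lower in 1 of 10 alternative settings, with peaks of maximum coverage 3 or more (1 of 20 against 28.6%, adjusted permutation p = 0.0292). Leukocyte markers had 9 of 22 (40.9% against 44.3%; p = 0.926, adjusted permutation p = 1), with 4 at CD8A and 3 at SPI1 and TYROBP. Epithelial and lung genes had 14 of 26 (53.8% against 39.9%; p = 0.200, adjusted permutation p = 0.256), with 8 at FOXA2, 6 at KRT8 and 4 at MUC1, and none at EPCAM or at AGER in the MHC.

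ZNF and histone genes, many of them in clusters, had fewer boundary peaks than matched lists. Numbered ZNF genes, most of which encode zinc finger proteins, had 181 of 509 (35.6% against 46.3%; p = 0.0002, the smallest possible, adjusted permutation p = 0.000657), with 30 at ZNF595, 16 at ZNF438 and 15 at ZNF524. This call ended in 1 of 10 alternative settings, with unmatched lists (ratio 0.888 in place of 0.767, adjusted permutation p = 0.0660). Replication-dependent histone genes had 16 of 69 (23.2% against 43.2%; p = 0.00120, adjusted permutation p = 0.00345), with 6 at H4C16 and 4 at H2AC20 and H2AC21, which share a peak. Of the 55 histone genes on chromosome 6, 8 had a boundary peak, as did 8 of the 14 elsewhere. In 2 of 10 alternative settings the call ended and the ratio to matched lists turned. It went from 0.536 to 1.504 without chromosome 6 (adjusted permutation p = 0.304) and to 1.12 with matching on surrounding peaks (0.846). Long genes of common fragile sites had a boundary peak in 5 of 20 cases (25% against 27.9%; p = 0.994, adjusted permutation p = 1) and a peak over the span in 19 of 20 (95% against 73.6%; p = 0.0368, adjusted permutation p = 0.0605). Over spans they passed as higher with unmatched lists (adjusted permutation p = 0.00307), with matching on surrounding peaks (0.0155) and without chromosome 6 (0.0151). With higher peaks the ratio, 1.29 for all peaks, was 1.09 (22878 highest), 0.947 (maximum coverage 3 or more) and 0.813 (4575 highest), none of which passed. Length was matched in 5 bins at most and not at all in the unmatched lists, and a longer span has more room for a peak. Peaks per 100 kb of span were 0.922 for MACROD2 (19 peaks), 0.717 for WWOX (8), 0.665 for IMMP2L (6), 0.501 for AUTS2 (6), 0.291 for CSMD1 (6) and 0.173 for CNTNAP2 (4).

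Over gene spans, 12 of the 23 lists passed the test. Those higher were ribosomal proteins (67.1%), snoRNA hosts (78.3%), housekeeping genes (92.0%), heat shock genes (88.9%), immediate early genes (87.5%), NRF2 targets (88.2%) and structured RNAs (80.6%). Those lower were antigen presentation, histones (26.1%), hepatocyte and erythroid markers (14.3%), olfactory receptors (6.92%) and ZNF genes (51.1%). Adjusted permutation p-values of these lists lay between 0.000575 and 0.0195. The ribosomal protein call ended in 1 of 7 alternative settings, with unmatched lists (ratio 1.11 in place of 1.57, adjusted permutation p = 0.357), and the histone call in 2 of 7. Of the 11 lists that did not pass, fragile site genes, cell cycle genes and DRIP-qPCR loci passed as higher in 3 of 7 settings each. Interferon-stimulated genes passed as lower in 2 of 7 and leukocyte markers in 1 of 7.

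Loci often used in DRIP-qPCR, a PCR assay of hybrids pulled down with S9.6, had a boundary peak in 6 of 8 cases (75% against 43.4%; p = 0.143, adjusted permutation p = 0.206). The list does not separate loci used as positive controls from those used as negative controls, so this share does not measure recovery. Maximum coverage was 14 at EGR1, 10 at CALM3, 6 at ACTB, 4 at APOE and BTBD19 and 3 at RPL13A. SNRPN had a peak of 5 inside its span, on chromosome 15 at 24954990 to 24955595, at the boundary of the overlapping gene SNURF. TFPT had none, and it lies in the leukocyte receptor complex (LRC) on chromosome 19, another region with alternate haplotypes among the mapped sequences.

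The peaks of highest total signal included the mitochondrial genome, nuclear copies of its genes and ribosomal DNA. Repeat annotation was not used. The mitochondrial genome was a single peak of 16569 bp with a maximum coverage of 7798 and 57.4% of the summed signal of all peaks. The highest on a chromosome, 1953, was on chromosome 1 at 629072 to 634932, over nuclear copies of mitochondrial genes such as MTCO1P12 and MTATP6P1, and touched the boundary of LOC101928626. On chromosome 21, peaks at the ribosomal DNA repeats reached up to 113, and one wholly inside RNA45SN2, at 8209446 to 8213341, reached 109. A peak at 9986 to 11809 of chromosome 5 reached 239, and one at 106628 to 111973 of chromosome 18, over ROCK1P1, reached 198. Among other genes with the highest boundary peaks, CIC reached 37 and carried 21 peaks over 27267 bp, and AMPD3 reached 33. FAM27C and FAM27E4 shared a peak of 32, and EEF2KMT reached 30. FARP2 and SEPTIN2 shared a peak of 29. TMEM87B reached 27, AP2A1 and TMEM80 24, and PRMT1 and PPM1B 23. The peak at AMPD3, on chromosome 11 at 10507889 to 10507966, was much narrower than the others. The genes with most peaks were the long genes TRAPPC9 (56), RBFOX3 (54), ASIC2 (53), GSE1 (50) and ZNF536 (47). Their peaks per 100 kb of span were 7.64, 9.34, 4.63, 9.83 and 9.59 in that order. The fragile site genes given above had 0.173 to 0.922. Genes chosen for having most peaks tend to be dense by selection, so this contrast does not show that fragile site genes are poor in peaks.

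Chromosomes differed beyond what gene class, length and density gave. Chromosome 6 was lowest, with a boundary peak at 175 of 1049 protein-coding genes (16.7%, 95% interval 14.5 to 19.1) against 40.1% in matched genes, a ratio of 0.416. Ratios were also low on X (0.576), 4 (0.641), 1 (0.769), 3 (0.861) and 11 (0.868). They were high on 22 (1.43), 16 (1.35), 20 (1.29), 14 (1.28), 10 (1.27), 9 (1.24), 17 (1.23), 8 (1.22), 2 (1.20) and 15 (1.19). These 16 chromosomes passed the test, with adjusted permutation p-values of 0.000329 to 0.000575 over 23 chromosomes. Chromosome copy number, GC content and expression were not matched, so their part in these differences is unknown. Clustered gene families were left out for chromosome 6 alone, in a test given below. Peak density ranged from 59.9 per Mb on chromosome 19, the most gene-dense, to 4.28 on chromosome 13, with 4.94 on chromosome 6. The MHC was part of the deficit: 4 of its 170 protein-coding genes (2.35%) had a boundary peak against 52.3% in matched genes, and chromosome 6 without it had 19.5% against 37.7%.

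**Figure D5:**
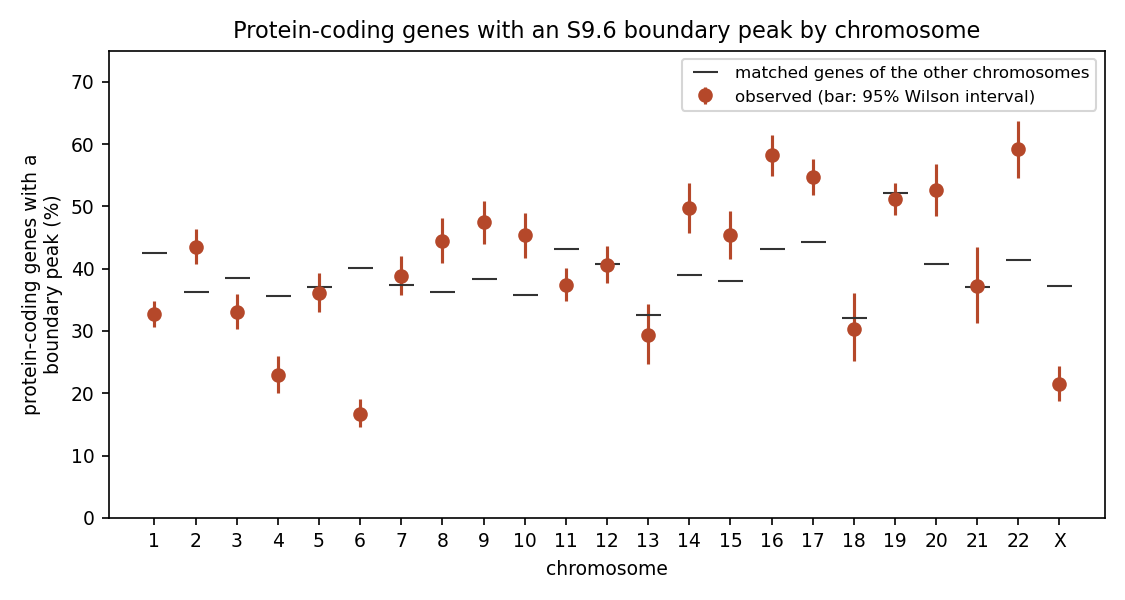
Protein-coding genes with an S9.6 boundary peak on each chromosome (percent, points with 95% Wilson intervals), beside matched genes of the other chromosomes (dashes). Chromosome 6 is at 16.7% against 40.1%, and chromosome 22 at 59.2% against 41.5%.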

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

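The tests of alternate haplotypes were chosen after the low MHC values were seen, and what each of the other explanations would predict was written down before its test was run. Signal also lay outside the sequences used in the tests. The mitochondrial genome reached a maximum coverage of 7798. Patches and alternate haplotypes held 1313 peaks on 223 sequences, unplaced and unlocalised sequences held 687 peaks, and chromosome Y held 53.

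A maximum coverage of 2 was found for 54.5% of the peaks. If they were chance overlaps of fragments spread evenly over each neighbourhood, they would lie at gene boundaries as often as after a local shift, but the ratio was 1.45 ± 0.0307 with 0 of 100 shifts as high. That argues against chance overlaps as the whole source, while some of these peaks may still be background. With peaks of maximum coverage 3 or more, 13 of 13 lists called at boundaries kept their call, but 3 more lists passed, so which lists stand apart depends in part on the low peaks, which the bound set in advance for kept calls alone did not count. Tagging of open chromatin without hybrids stays open, and no biological explanation was tested because the design gives a single condition.

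Chromosome 6 had few boundary peaks for its genes. Gene class, length and density did not account for it (ratio to matched genes 0.416), nor did its clustered gene families, since the ratio was 0.568 without genes between 25 and 34 Mb. Reads divided between the chromosome and its alternate haplotypes are a candidate explanation for the MHC, where the ratio was 0.0450. The LRC on chromosome 19, which also has alternates, had a ratio of 0.398, whereas the rest of chromosome 19 had 1.00. Expression was not matched in either region, so these ratios do not show that divided reads were the cause. Outside the MHC the ratio was still 0.516, so the haplotypes leave most of chromosome 6 unexplained, and fewer copies of it in these cells cannot be told apart without input coverage (4.94 peaks per Mb).

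Ribosomal DNA and mitochondrial DNA were among the regions of highest signal. If many copies in the cells were collapsed onto few in the assembly with no preference within the repeat, coverage would be even along the ribosomal repeat. On chromosome 21 the mean coverage of 24 peaks outside the 45S genes was 0.621 times that of 14 peaks overlapping them. However, 37169 of the 95722 bp of those 14 peaks (38.8%) lay in 45S genes, so this test decides nothing, and copy number and hybrid signal cannot be told apart here. No biological explanation was tested.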

How the results depend on the processing

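The local shift, the shuffle with no span left out, matching on surrounding peaks, peaks of maximum coverage 3 or more, genes of at least 2 kb, and lists without chromosome 6 or without MHC and LRC genes were tests chosen after the data were seen. The excess of peaks at boundaries kept its direction and passed in all 8 alternatives run, with ratios of 2.29 to 6.94. With protein-coding genes alone, the ratio of summits inside genes turned from 0.943 to 1.03, and the cause was not tested. The share of protein-coding genes with a boundary peak, 40.1%, was 33.2% with the 22878 highest peaks and 14.9% with the 4575 highest, 36.7% with the summit in the window, and 35.3% and 45.8% with windows of 500 and 2000 bp. Fewer peaks or narrower windows give lower shares by construction. The inside share of summits, 48.9%, passed the test below equal shares at 46.7% with the 22878 highest peaks and 38.8% with the 4575 highest. With no boundary left out it also passed below equal shares, at 45.7%. A summit near several boundaries then counted once for each, so those counts are not independent. With the middle of the peak the inside share passed above equal shares, at 53.1%, and the cause of these differences was not tested. Lists lower at boundaries fell from 4 to 2 with matching on surrounding peaks. Lists lower over spans fell from 5 to 3 with that matching and to 3 without chromosome 6. For the height of boundary peaks, 0 lists were higher and 0 lower with either set of higher peaks, against 1 each. Olfactory receptors then had fewer members with a peak (5 against 14 with the 22878 highest). Structured RNAs kept 25 with that set, while their matched median rose from 3 to 4. With the 4575 highest they had 18, and a median of 8.5 compared with 7.5. The ratio of histone genes turned from 0.536 to 1.12 with matching on surrounding peaks and 1.504 without chromosome 6, and over spans from 0.554 to 1.14 and 1.64. That of antigen presentation genes over spans turned from 0.551 to 1.08 without chromosome 6 and 1.09 without MHC and LRC genes, where members without a peak were left out. None of these turned ratios passed the test. Of the 13 lists called at boundaries, 12 were kept with the 22878 highest peaks, 11 with the 4575 highest, 10 with windows of 500 bp, 13 with 2000 bp, 10 with unmatched lists, 8 with matching on surrounding peaks, 10 without chromosome 6 and 13 without MHC and LRC genes. Among boundary calls, those lost in the most alternatives were of NRF2 targets (6 of 10) and R-loop factors (5 of 10), and the cause was not tested. Lists of m6A factors and interferon-stimulated genes, not called with all peaks, each passed in 2 of 10. Matching on GC content, all transcripts, gene ends, GC skew and base composition were not run, since no sequence or transcript models were used. No paired analysis was possible because there was 1 library per antibody. Depth is unknown, and with a median maximum of 2 fragments the absence of a peak limits little.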

Other observations

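Transfer RNA genes also had a lower share with a boundary peak on chromosome 6. Outside chromosome 6, 176 of 288 tRNA genes (61.1%, 95% interval 55.4 to 66.6) had a boundary peak, whereas 18 of the 155 on chromosome 6 did. For miRNA genes the counts were 348 of 1840 elsewhere and 1 of 71 on chromosome 6, and for snoRNA genes 116 of 1141 and 0 of 55. Genes for rRNA had no member on chromosome 6. These splits were made after the chromosome values were seen and were not tested.

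Some chromosome starts carried high peaks. Within the first 20 kb of the 23 chromosomes there were 19 peaks on 10 of them, with a median maximum coverage of 4. Whether the other starts hold assembled sequence there was not examined. On chromosomes 1, 3, 5, 7, 10, 12 and 18 the first began between positions 9980 and 9998, where the assembled sequence follows the leading gap, and maximum coverage there ranged from 14 on chromosome 18 to 239 on chromosome 5. The other 12 peaks, on chromosomes 4, 9, 12 and X, reached 2 to 11. On chromosome 3 this peak reached 46 and touched the boundaries of LINC01986 and LOC124905351.

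Along chromosome 6 outside the clustered region the low share was spread over both arms. Protein-coding genes below 25 Mb had a boundary peak in 20.9% of cases against 33.4% in matched genes, and those from 34 to 60 Mb in 28.4% against 42.6%. Those above 60 Mb had 16.6% against 34%. Of the 42 genes of the LRC on chromosome 19, 9 had a boundary peak (21.4% against 53.8%), and the region held 18 peaks on the chromosome itself and 31 on its 8 alternate haplotypes with peaks.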
